A study of Mus musculus with 6 samples.

How the data were processed

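Whole-transcriptome RNA-seq libraries were made from cultured cancer-associated fibroblasts, the fibroblasts of a tumour, isolated from mammary tumours of MMTV-PyMT mice. These mice carry a polyomavirus middle T transgene that gives mammary tumours. The mice were heterozygous (HET) or homozygous (KO) for a targeted allele of Hic-5, encoded by Tgfb1i1. There were 3 libraries of each labelled genotype and 6 in all. Per the labels' protocols, total RNA was taken with Trizol and made into stranded libraries after removal of ribosomal RNA. The submitters' processing notes name Partek, cutadapt 1.2.1 and Bowtie2, and the builds GRCm38 and mm10. The annotation and the counting method were not given in the sources used here.

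The authors deposited an estimated count per gene and library, not scaled between libraries, and 85.0% of the values were whole numbers. The authors also deposited RPKM values, scaled by gene length and by library total. Over 12508 genes, the ratio of the deposited estimated count to RPKM kept its constant within each library to 0.0013%, so both tables hold the same measurement. Each table had 48408 rows. In 30 rows a biotype word stood in place of the gene and the values were moved by 1 column, or by 2 columns in 3 of these rows, so these rows were left out. A further 7 symbols stood on more than 1 row and were summed. This left 48368 symbols, of which 29661 had any count. Totals ran from 24954273 to 42470598 estimated counts per library. A floor of 3 counts corresponded to 0.0706 to 0.1202 CPM. Floors cover counting error only, since the reads carried no molecular identifiers.

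The groups were taken from the genotype label of each library. The series text speaks of technical triplicates, while the titles carry different numbers except for 1 number shared by a HET and a KO title (HET replicate 3 and KO replicate 3). Nothing else says whether the libraries came from separate animals or cultures, so p-values measure only the spread between these libraries. That spread was far beyond counting noise (chi-square per degree of freedom of 173 to 382 within a label), so libraries of a label are not repeat sequencing of 1 library. Whether it lies between animals, cultures or RNA preparations is not given in the sources used here. Replicate numbers were given in accession order and pair no libraries. Because Tgfb1i1 transcript was plainly present in part of the KO libraries, groups are called by their labels throughout.

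Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr at its defaults, scaled by TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, KO against HET, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of F. CPM values are counts relative to library totals scaled by TMM factors, given as mean ± SD. Gene lists were tested with camera from limma 3.58.1, which compares a list with all other tested genes, at a preset correlation of 0.01. They were tested again with an estimated correlation and with fry. Lists needed at least 5 tested members, and Tgfb1i1 was left out of all of them. Of the lists, 29 were tested, and the list of sex-linked genes had 1 tested member and was not. Genes within 10 Mb of Tgfb1i1 were compared with other tested genes by Fisher's exact test, with positions from GENCODE M21 (GRCm38).

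The named genes followed a rule. It took Tgfb1i1 first, and then the genes of largest change among those past the adjusted threshold. With fewer than 5 such genes in a direction, it took the 5 with the smallest unadjusted p in that direction, leaving out unnamed gene models. In each list it took up to 4 members with the smallest unadjusted p. The design, the gene lists, the rule and the alternatives were fixed before the data were examined, except the alternatives and tests named as chosen later. The alternatives were other scaling factors, filters on low counts, DESeq2 1.42.0, limma-voom, limma on log2(RPKM + 1) and log2(RPKM + 0.1), a term for the shared title number, and leaving out each library in turn. Leaving out both libraries of the shared title number was added after seeing the data.

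The count test was tested on simulated data drawn for 17584 genes from these libraries' means and sizes, with 200 genes changed. Genes were drawn at a dispersion trend, without spread between genes around it and without a library standing apart. Recovery in the real data can therefore be lower. At the dispersion trend of these libraries the count test recovered 4% of genes changed by a fold of 2, 32% at a fold of 4, 64% at a fold of 8 and 88% at a fold of 16, with 3 unchanged genes called. At a dispersion of 0.05 these shares were 36%, 98%, 100% and 100%, with 7 unchanged genes called. In 20 simulated draws without change and without correlation between genes, camera called 2 lists in total.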

Results

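RNA was measured in 6 libraries of cultured fibroblasts from mouse mammary tumours, 3 labelled heterozygous (HET) and 3 labelled knockout (KO) for Hic-5, a LIM-domain adaptor of focal adhesions related to paxillin. The series addresses differential expression between these genotypes. Totals were 30274860, 37930851 and 25668423 estimated counts in HET replicates 1 to 3, and 42470598, 35042817 and 24954273 in KO replicates 1 to 3. After filtering, 17584 genes were tested.

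Tgfb1i1, which encodes Hic-5 and lies on chromosome 7 from 128246812 to 128255699 (GRCm38), was nearly absent from only 1 of the 3 libraries labelled KO. It stood at 223, 348 and 125 CPM in HET replicates 1 to 3. It stood at 90.4 CPM in KO replicate 1, 0.232 CPM in KO replicate 2 and 156 CPM in KO replicate 3. KO replicate 3 lay within the range of the HET libraries, and KO replicate 1 lay under it. The means were 231.9 ± 112 CPM for HET and 82.3 ± 78.3 CPM for KO (SD, n = 3 each). The log2 fold change was -1.50 ± 1.54 (SE), with an adjusted p of 0.756 in edgeR's quasi-likelihood test. Transcript of the targeted gene was thus present in KO replicates 1 and 3, as far as gene totals show, although KO replicate 1 lay under every HET library. The estimated counts do not resolve exons, so transcript of a disrupted allele is not told apart from intact transcript. All directions below compare libraries labelled KO with libraries labelled HET.

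**Figure D1:**
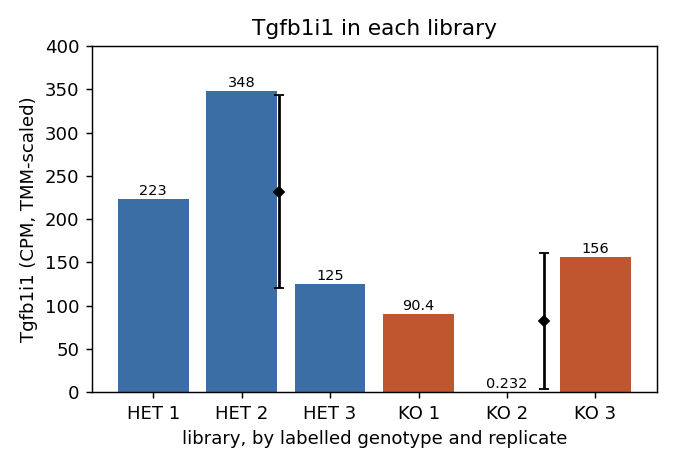
Tgfb1i1 in CPM (vertical axis) in each library (horizontal axis), with libraries labelled HET in blue and KO in orange. Diamonds with bars give the mean and SD of the 3 libraries of a label. KO replicate 2 stood at 0.232 CPM, and KO replicate 3, at 156 CPM, stood above HET replicate 3 at 125 CPM.

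KO replicate 2 also stood apart in fibroblast genes. Col1a2, a chain of type I collagen, stood at 0.491 CPM there and between 577 and 5109 CPM in the other 5 libraries. Acta2, smooth muscle actin, stood at 45.5 CPM against 1338 to 6455 CPM. Vim, the intermediate filament gene of mesenchymal cells, stood at 2870 CPM, within the 2020 to 4387 CPM of the others. The keratin genes Krt8 and Krt18 reached 13.7 and 37.9 CPM in KO replicate 2 and at most 2.46 and 2.93 CPM elsewhere. The first principal component held 42.7% of the variance and placed KO replicate 2 at 154, with the others between -79.2 and 18.2. Ptprc, the pan-leukocyte gene, stood at 8.19 CPM in HET replicate 2 and 5.67 CPM in KO replicate 3, and at 0.0455 CPM or less elsewhere. Correlations of log2 CPM across genes ran from 0.904 to 0.945 within HET, 0.858 to 0.904 within KO and 0.810 to 0.941 between labels. Libraries of one label differed far beyond counting noise, with a chi-square per degree of freedom of 173 to 382.

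No gene passed the adjusted threshold between KO and HET in edgeR, and the smallest adjusted p was 0.579. At an unadjusted p under 0.05 there were 1511 genes, 756 higher and 755 lower in KO, where chance alone would give 879. DESeq2 called 240 genes at its adjusted p, 71 higher and 169 lower in KO, and 212 of these differed at least 2-fold. Limma-voom called 0 genes, with 1538 at an unadjusted p under 0.05. The groups did not overlap in 2729 genes, 15.5% of those tested, where chance gives 10% and where another split of the same libraries gave 3767. The count at an unadjusted p was 633 without HET replicate 2, 923 without KO replicate 2 and 2213 without KO replicate 3. With library size alone as the scaling, the median gene moved to 0.15 (log2), and 1200 genes were higher and 532 lower at an unadjusted p under 0.05.

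The genes with the smallest unadjusted p that were lower in KO were not past the edgeR threshold (adjusted p = 0.579 for each). They included a basement membrane gene, a Wnt antagonist and a growth factor gene. Nid2, the basement membrane protein nidogen 2 (chromosome 14, 19751265 to 19811787), had 129.9 ± 56.8 CPM in HET and 8.63 ± 2.62 CPM in KO, a log2 fold change of -3.91 ± 0.44 (SE). Sfrp1, a secreted Wnt antagonist (chromosome 8, 23411502 to 23449632), had 1875 ± 1171 and 92.3 ± 17.3 CPM (log2 fold change -4.35 ± 0.54). Igf1, insulin-like growth factor 1 (chromosome 10, 87858265 to 87937042), had 186 ± 102 and 18.6 ± 7.34 CPM (-3.33 ± 0.51). H2-DMb1, a chaperone of MHC class II peptide loading (chromosome 17, 34153072 to 34160230), had 11.6 ± 2.43 and 2.04 ± 0.101 CPM (-2.50 ± 0.31). Fam46b had 28.8 ± 6.57 and 5.76 ± 0.929 CPM (-2.32 ± 0.29). For each of these genes, every library labelled HET lay above every library labelled KO, and DESeq2 placed all 5 past its threshold, with adjusted p between 7.5e-14 and 4.0e-07. As the genes were picked by their p in the same libraries, neither is independent support. DESeq2 called 632 genes in a split that mixes the labels, against 240 by the labels.

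On the higher side, also not past the edgeR threshold (adjusted p = 0.579 for each), Lpcat1, a lysophosphatidylcholine acyltransferase (chromosome 13, 73467197 to 73516422), had 20.7 ± 1.88 CPM in HET and 63.3 ± 17.8 CPM in KO, a log2 fold change of 1.61 ± 0.27. Etv4, an ETS transcription factor (chromosome 11, 101769742 to 101785371), had 11.1 ± 4.43 and 53 ± 16.3 CPM (2.26 ± 0.39). Arl4c, a small GTPase (chromosome 1, 88673125 to 88702221), had 28.8 ± 7.67 and 87.9 ± 20.1 CPM (1.61 ± 0.30). Grk6, a kinase of G protein-coupled receptors (chromosome 13, 55445072 to 55460927), had 50.1 ± 5.59 and 95.8 ± 8.51 CPM (0.94 ± 0.18). DESeq2 placed these 4 past its threshold, which is not independent support either, as they were picked in the same way. Zic5 was near the floor, at 0 to 0.0284 CPM in HET and 0.317 to 0.728 CPM in KO.

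**Figure D2:**
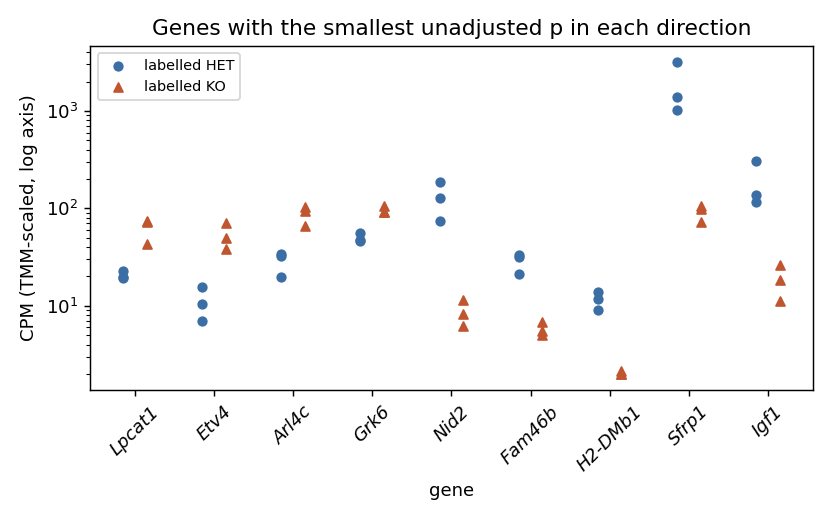
CPM on a log axis (vertical) for each named gene (horizontal), with 1 point per library, circles for libraries labelled HET and triangles for KO. The groups do not overlap for any gene drawn, as for Nid2 with 74.9 to 188 CPM in HET and 6.19 to 11.4 CPM in KO. None passed edgeR's adjusted threshold. The genes were picked by their unadjusted p in these libraries, so the lack of overlap is not independent support. Zic5 is left out because HET libraries stand at 0.

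Extracellular matrix genes were mostly lower in libraries labelled KO. Of 29 lists tested, 16 passed camera at its preset correlation, 3 higher and 13 lower, and none passed with an estimated correlation (smallest adjusted p = 0.352). No member of any list passed edgeR's test over all genes. DESeq2 called some lower in KO, Nid2, Prelp and Col3a1 among them, and some higher, Mmp9, Itga6 and Esr1 among them. In 10 of the 16 lists the list means of the libraries overlapped between the labels. Fibrillar and associated collagens had 14 of 18 members lower, with a median log2 fold change of -1.54 (camera adjusted p = 2.7e-05; adjusted p = 0.352 with an estimated correlation). Col3a1 had 866 ± 912 CPM in HET and 40.9 ± 44.1 CPM in KO, and Col5a1 had 700.1 ± 545 and 166.8 ± 49.3 CPM. Both were highest in HET replicate 1, at 1873 and 1271 CPM. In HET replicate 3 and KO replicate 3, Col3a1 stood at 95.4 and 91.3 CPM and Col5a1 at 186 and 223 CPM. The mean of the collagen list was 1.49, 0.97 and 0.25 in HET replicates 1 to 3. It was -0.81, -1.58 and -0.32 in KO replicates 1 to 3. Matrix glycoproteins and proteoglycans had 29 of 38 members lower, with a median of -1.03 (camera adjusted p = 2.7e-08; adjusted p = 0.352 with an estimated correlation). Prelp, a leucine-rich proteoglycan, had 1739 ± 1100 and 22.8 ± 19 CPM, and Sparc, a collagen-binding glycoprotein, had 5792 ± 3581 and 1432 ± 483 CPM. The mean of this list was -2.28 (log2, from the 6-library mean) in KO replicate 2, against -0.03 and -0.41 in KO replicates 1 and 3. Its median was -0.60 without HET replicate 1 and -1.78 without KO replicate 1.

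Basement membrane genes had 13 of 22 members lower, with a median of -0.55 (camera adjusted p = 7.5e-04; adjusted p = 0.370 with an estimated correlation). Adjusted over the list alone, 3 members passed edgeR, namely Nid2, Col18a1 and Col4a5. Col18a1 had 17.5 ± 2.38 CPM in HET and 4.61 ± 1.13 CPM in KO. The mixed test of fry, which asks whether members change in either direction, placed this list (adjusted p = 0.00026) and the adipocyte list (adjusted p = 0.016) past the threshold. The directional test of fry placed neither past it (adjusted p = 0.250 and 0.247). Without KO replicate 1 the basement membrane list had a median of -0.41 and a camera adjusted p of 0.141. Collagen processing and crosslinking had 19 of 27 members lower, with a median of -0.74 (camera adjusted p = 0.0056; adjusted p = 0.478 with an estimated correlation), and passed neither without HET replicate 1 (median -0.13, adjusted p = 0.205) nor without KO replicate 2 (-0.47, 0.0919), and its median was -0.42 without HET replicate 2. P4ha2, a collagen prolyl hydroxylase, had 221 ± 164 and 31.6 ± 19.1 CPM, and Adamts2, a procollagen peptidase, had 244 ± 229.6 and 34.3 ± 20.4 CPM. Matrix proteases and inhibitors had 23 of 36 members lower, with a median of -0.33 (camera adjusted p = 0.026; adjusted p = 0.429 with an estimated correlation). This call was lost without HET replicate 2 (median -0.22, adjusted p = 0.199) and without KO replicate 2 (0.178), where the median, at -0.38, was no smaller; the median was -0.61 without KO replicate 1 and -0.67 without KO replicate 3. Mmp28 had 10.1 ± 3.59 and 2.27 ± 0.549 CPM, while Mmp9, a gelatinase, had 0.299 ± 0.162 and 9.82 ± 11.8 CPM.

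Contractile and myofibroblast genes had 27 of 31 members lower, with a median of -0.63 (camera adjusted p = 3.0e-06; adjusted p = 0.429 with an estimated correlation). The list mean was -1.59 in KO replicate 2, and KO replicate 3 (0.19) stood above HET replicate 3 (0.0026). Cnn1, calponin, had 457 ± 202 CPM in HET and 85.2 ± 65.5 CPM in KO, and Mylk, myosin light chain kinase, had 28.5 ± 26.5 and 4.33 ± 1.74 CPM. Cdh2, N-cadherin, had 74.5 ± 21.1 and 154 ± 24.7 CPM. Without KO replicate 3 the median of the contractile list was -1.02. Pericyte and smooth muscle markers had 10 of 14 members lower, with a median of -1.64 (camera adjusted p = 5.0e-05; adjusted p = 0.370 with an estimated correlation). Their median was -2.54 without KO replicate 3. The mean of these markers was -2.31 in KO replicate 2 and 2.11 in HET replicate 2, while KO replicate 3 (0.14) stood close to HET replicate 3 (0.25). Ndufa4l2 had 21.9 ± 21.5 and 0.339 ± 0.432 CPM, and Actg2, an actin of smooth muscle, had 336 ± 242 and 48.6 ± 47.0 CPM. The lists of focal adhesion adaptors and kinases (13 of 27 higher, median -0.02, adjusted p = 0.625), integrins (10 of 19 higher, median 0.19, 0.820), SRF-MRTF targets (13 of 31 higher, median -0.13, 0.125), YAP-TAZ targets (14 of 27 higher, median 0.02, 0.820) and the TGF-beta pathway (15 of 29 higher, median 0.03, 0.404) did not pass camera. For the YAP-TAZ and TGF-beta lists the median was above 0 while the test pointed down. Within them Vcl, vinculin, had 876 ± 173 and 516 ± 23.4 CPM, and Tns2, tensin 2, had 77.9 ± 31.7 and 31.8 ± 8.78 CPM. In the other direction, Git1 had 60.7 ± 6.51 and 94.0 ± 9.71 CPM, and Bcar1 had 107 ± 12.8 and 186 ± 59.7 CPM. Itga6 had 13.7 ± 1.73 and 93.8 ± 84.6 CPM, and Itga1 had 26.4 ± 13.8 and 6.29 ± 4.08 CPM. Ier2 had 25.4 ± 4.10 and 40.2 ± 11 CPM, and Fos had 10.0 ± 2.72 and 5.15 ± 2.10 CPM. Gadd45a had 21.6 ± 3.65 and 11.4 ± 1.04 CPM, and Ajuba had 57.2 ± 10.3 and 102.9 ± 34.0 CPM. Cdkn2b, a cyclin-dependent kinase inhibitor, had 84.9 ± 35.9 and 17.0 ± 8.75 CPM, and Smad6, an inhibitory Smad, had 58.4 ± 31.5 and 19.6 ± 3.98 CPM. The TGF-beta list passed as lower without KO replicate 3 (adjusted p = 0.0221) and without both libraries of the shared title number (1.3e-04). The SRF-MRTF list passed as lower without HET replicate 3 (0.0184), without both libraries of the shared title number (0.0262) and on both filtered RPKM scales (0.0090 and 0.0102).

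Both cell cycle lists passed camera as higher in libraries labelled KO, although their means overlapped between the labels. The S phase list had 31 of 32 members higher, with a median of 1.49 (camera adjusted p = 1.4e-13; adjusted p = 0.429 with an estimated correlation), and the G2 and M phase list had all 34 members higher, with a median of 0.90 (6.3e-10; adjusted p = 0.478 with an estimated correlation). Mcm4, of the replicative helicase, had 43.1 ± 24.2 CPM in HET and 128.6 ± 88.7 CPM in KO, and Prim1, a primase subunit, had 8.63 ± 5.01 and 33.3 ± 28.6 CPM. Cenpe, a kinetochore motor, had 17.0 ± 10.6 and 36.7 ± 4.74 CPM, and Foxm1 had 34.8 ± 26.3 and 96.2 ± 59.3 CPM. The S phase mean was lowest in HET replicate 2 (-1.83) and highest in KO replicate 2 (1.89), and HET replicate 1 (0.37) stood above KO replicates 1 (0.26) and 3 (-0.02). The G2 and M phase mean was likewise lowest in HET replicate 2 (-2.28) and highest in KO replicate 2 (1.37), and HET replicate 1 (0.77) stood above KO replicates 1 (0.52) and 3 (0.0054). Without KO replicate 2 the medians were 0.58 for S phase and 0.39 for G2 and M phase, without HET replicate 2 they were 1.01 and 0.41, and without HET replicate 1 they were 2.22 and 1.76.

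Hypoxia and glycolysis genes had 29 of 31 members lower in KO, with a median of -0.76 (camera adjusted p = 1.1e-07; adjusted p = 0.429 with an estimated correlation). The list mean was 0.94 and 0.82 in HET replicates 1 and 2, while HET replicate 3 (-0.33) stood below KO replicate 3 (0.15). The median was -0.42 without HET replicate 1. Pdk1, a kinase that restrains pyruvate dehydrogenase, had 115 ± 79.9 CPM in HET and 23.7 ± 5.94 CPM in KO, and Bnip3, a mitophagy receptor, had 121 ± 69.6 and 20.6 ± 8.92 CPM. Cholesterol synthesis genes had 21 of 25 members lower, with a median of -0.45 (camera adjusted p = 9.3e-05; adjusted p = 0.370 with an estimated correlation). Lss, lanosterol synthase, had 53.9 ± 5.96 and 32.6 ± 5.75 CPM, and Sqle, squalene epoxidase, had 97.1 ± 10.8 and 62.9 ± 11.7 CPM. Autophagy and lysosome genes had 29 of 35 members lower, with a median of -0.29 (camera adjusted p = 7.1e-04; adjusted p = 0.429 with an estimated correlation). Their median was -0.15 without HET replicate 2. Wipi1 had 123 ± 20.1 and 72.3 ± 9.53 CPM, and Bnip3l had 195.6 ± 18.9 and 100.2 ± 40.3 CPM.

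The p53 targets had 23 of 28 members lower, with a median of -0.36 (camera adjusted p = 0.0021; adjusted p = 0.583 with an estimated correlation), and did not pass without KO replicate 2 (median -0.16, adjusted p = 0.347), without HET replicate 3 (-0.20, 0.0527) or without both libraries of the shared title number (-0.41, 0.0752), while the median was -0.93 without KO replicate 1. Phlda3 had 283 ± 54.4 CPM in HET and 126 ± 74.8 CPM in KO, and Plk2 had 161 ± 64.8 and 281 ± 44.5 CPM. Oxidative stress genes had 22 of 30 members lower, with a median of -0.10 (camera adjusted p = 0.0133; adjusted p = 0.478 with an estimated correlation). Without HET replicate 3 this call was lost (median -0.08, adjusted p = 0.0786), as it was without KO replicate 1 (0.01, 0.162), and with library size alone as the scaling the median was 0.03. It was -0.28 without HET replicate 1, -0.21 without KO replicate 2 and -0.49 without KO replicate 3. Me1, malic enzyme, had 167 ± 40.3 and 106 ± 5.19 CPM, and Sod3, extracellular superoxide dismutase, had 435 ± 139 and 167 ± 115 CPM. The unfolded protein response and amino acid stress list did not pass camera (13 of 32 higher, median -0.08, adjusted p = 0.116), but passed as lower without HET replicate 3 (0.0269) and on both filtered RPKM scales (0.0175 and 0.0180). Its member Ddit3 had 69.2 ± 15.8 and 32.2 ± 7.71 CPM, and Trib3 had 54.1 ± 49.2 and 11.4 ± 2.02 CPM.

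Inflammatory and immune lists did not pass camera in the edgeR fit of all 6 libraries. Inflammatory fibroblast cytokines and chemokines had 21 of 34 members lower, with a median of -0.44 (adjusted p = 0.334). They passed as lower without KO replicate 3 (adjusted p = 0.0465) and on both filtered RPKM scales (0.0482 and 0.0365). Complement C3 had 158 ± 91.3 CPM in HET and 24.3 ± 4.48 CPM in KO, and Lif, a cytokine of the interleukin 6 family, had 17.4 ± 7.53 and 53.5 ± 23.4 CPM. Interferon-stimulated genes had 27 of 39 members higher, with a median of 0.39 (adjusted p = 0.602). The list mean was 1.66 in KO replicate 2, and without that library the list passed as lower, with a median of -0.70 (adjusted p = 3.6e-06). It passed as higher without KO replicate 1 (median 0.74, adjusted p = 0.0112), without KO replicate 3 (0.50, 0.0211) and without both libraries of the shared title number (0.97, 0.0103). Gbp2 had 32.6 ± 22.9 and 11.4 ± 4.82 CPM, and Ifi44 had 1.14 ± 0.914 and 10.1 ± 13.4 CPM. The MHC class II list had 4 of 8 members higher, with a median of 0.14 while the test pointed down (adjusted p = 0.120), and 1 member, H2-DMb1, passed edgeR adjusted over the list alone. The list also holds Slpi and Saa3, which are not MHC genes. Slpi had 6.25 ± 5.50 and 72.3 ± 120.1 CPM, a KO mean carried by KO replicate 2. Slpi stood at 211 CPM there and at 0.159 and 5.79 CPM in KO replicates 1 and 3. Without KO replicate 2 its log2 fold change was -1.11. This list passed as lower without KO replicate 3 (median -2.75, adjusted p = 0.0018), without HET replicate 1 (-0.26, 0.0420) and without both libraries of the shared title number (-2.50, 0.0057). Its mean was 1.89 in HET replicate 2 and 2.13 in KO replicate 3, where Ptprc was highest, and -2.02 to 0.61 elsewhere.

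Among markers of other cell types, mammary epithelium genes had 17 of 19 members higher in KO, with a median of 2.04 (camera adjusted p = 0.0010; adjusted p = 0.429 with an estimated correlation). Without KO replicate 2 the median was 0.42 and the call was lost (adjusted p = 0.178), as it was with limma-voom (median 0.71, adjusted p = 0.0578). Krt8 had 0.334 ± 0.132 CPM in HET and 5.48 ± 7.24 CPM in KO, and Esr1, the estrogen receptor, had 3.13 ± 1.30 and 21.5 ± 15.5 CPM. Adipocyte and preadipocyte markers had 10 of 13 members lower, with a median of -0.65 (camera adjusted p = 0.0030; adjusted p = 0.352 with an estimated correlation). The call was lost on log2(RPKM + 1), with a median of -0.29 (adjusted p = 0.106), and on log2(RPKM + 0.1), with a median of -0.69 (0.0859), while the median was -1.37 without KO replicate 1 and -1.04 without KO replicate 3. Pparg had 16.2 ± 8.67 and 3.05 ± 2.82 CPM, and Lpl, lipoprotein lipase, had 252 ± 191 and 71.7 ± 26.1 CPM. Macrophage and other leukocyte markers did not pass (4 of 11 higher, median -0.39, adjusted p = 0.820), with list means of 2.92 in HET replicate 2 and 2.49 in KO replicate 3 and of -0.83 or lower elsewhere. Without HET replicate 2 this list passed as higher, with a median of 2.27 (adjusted p = 0.0203), and without both libraries of the shared title number it passed as lower, with a median of -2.99 (0.0078). Csf1r had 27.0 ± 14.6 and 9.86 ± 12.7 CPM, and Cd14 had 11.5 ± 5.03 and 14.4 ± 4.33 CPM. Endothelial (4 of 10 higher, median -0.27, adjusted p = 0.602), skeletal muscle (2 of 5 higher, median -0.38, 0.840) and Schwann cell markers (7 of 11 higher, median 0.15, 0.610) did not pass, and for skeletal muscle the mean (0.09) and for Schwann cells the test differed in sign from the median. The endothelial list passed as lower without KO replicate 3 (adjusted p = 0.0146), without both libraries of the shared title number (3.5e-04) and with no filter on counts (0.0481) or RPKM (0.0336). Flt1 had 49.1 ± 12.7 and 19.2 ± 12.9 CPM, and Tek had 1.87 ± 0.365 and 0.413 ± 0.673 CPM. In the other direction, Esam had 0.273 ± 0.150 and 0.934 ± 0.502 CPM, and Kdr had 1.04 ± 1.28 and 4.98 ± 6.76 CPM. Acta1 had 166 ± 50.7 and 72.7 ± 85.4 CPM, and Neb had 4.36 ± 2.48 and 1.84 ± 1.27 CPM. Of the same list, Ttn was higher, with 0.264 ± 0.0826 and 1.14 ± 1.10 CPM, as was Mylpf, with 0.498 ± 0.0460 and 1.14 ± 0.947 CPM. Pmp22 had 340 ± 67.3 and 106.6 ± 34.1 CPM and passed edgeR adjusted over the Schwann cell list alone, and Gap43 had 0.949 ± 1.25 and 30.2 ± 50.4 CPM. Gap43 stood at 88.3 CPM in KO replicate 1 and at 0.517 and 1.67 CPM in KO replicates 2 and 3.

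**Figure D3:**
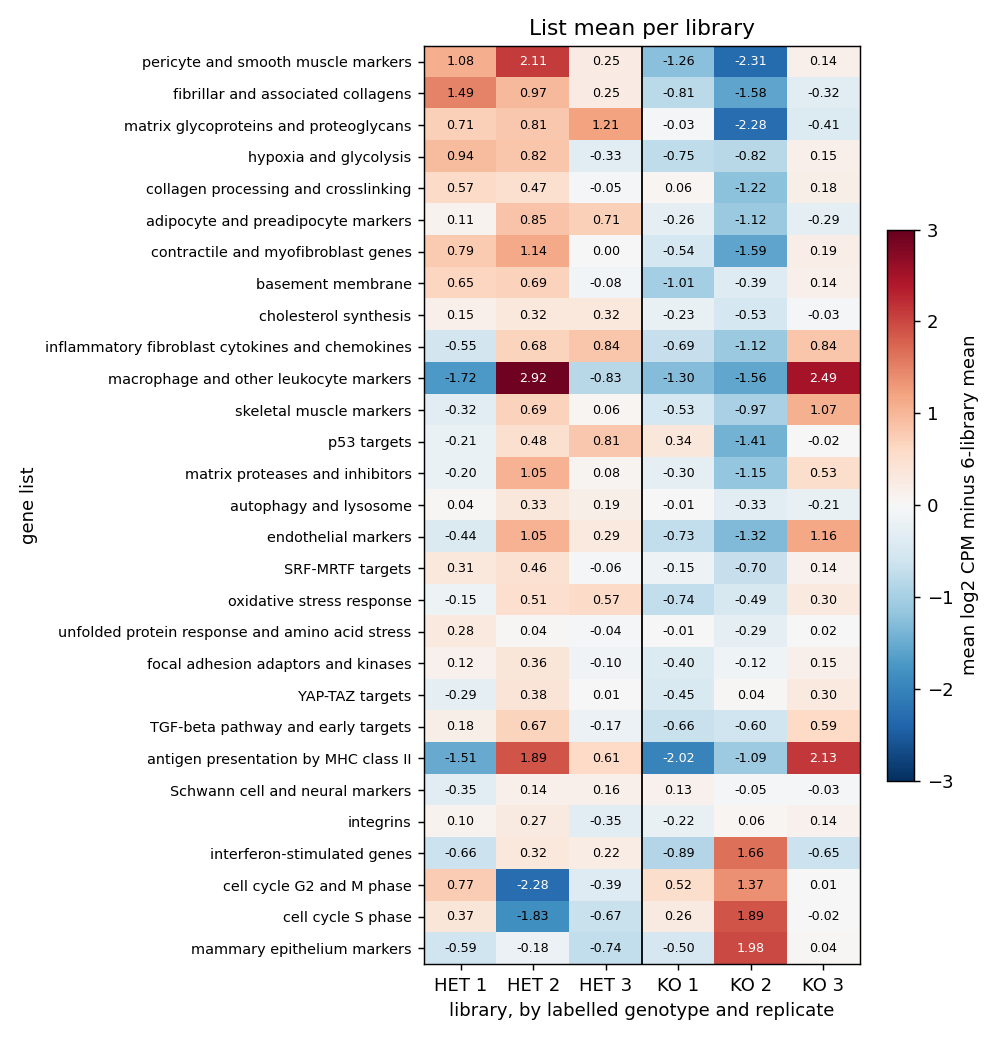
Mean log2 CPM of each gene list (rows) in each library (columns), as the difference from the mean of the 6 libraries, with red above and blue below. Matrix glycoproteins reach -2.28 and S phase genes 1.89 in KO replicate 2, and leukocyte markers reach 2.92 in HET replicate 2 and 2.49 in KO replicate 3.

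A targeted allele can carry flanking sequence of another strain, so genes near Tgfb1i1 were compared with the rest. Of 203 tested genes within 10 Mb, 0 passed edgeR's adjusted threshold, as did 0 of 16777 other genes. With no gene past the threshold anywhere, these shares could not differ and say nothing of flanking sequence. At an unadjusted p under 0.05 there were 18 near genes (8.87%) and 1446 others (8.62%), and the shares did not differ in Fisher's exact test (two-sided p = 0.900).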

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

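With edgeR, 0 genes passed under every scaling, filter and left-out library tried, as with limma-voom and limma on RPKM, while DESeq2 called 240 genes, 212 of them at least 2-fold; the cause was not tested. Tgfb1i1 kept its direction and missed the threshold in all fits, from -3.97 with limma-voom to -0.93 without KO replicate 2, and from -2.36 (without KO replicate 3) to -0.93 with 1 library left out. As no gene passed in any of these edgeR fits, the share past the threshold near Tgfb1i1 could only be 0 and says nothing of its stability. Lists past camera numbered 13 (without KO replicate 2) to 21 (without KO replicate 3) and 21 without both libraries of the shared title number, an alternative chosen after seeing the data. Fry called 0 lists for one direction and 2 for either direction. Over 473 pairs of list and alternative, 14 list calls were lost, in 7 lists, and 25 gained, in 8 lists. At an unadjusted p, genes numbered 633 to 2213 with 1 library left out. DESeq2 placed 35 of 120 named genes past its threshold, 9 higher and 26 lower. No paired analysis was possible because only 1 number is shared between a HET and a KO title. Depth limits genes near 0.1202 CPM, the highest floor.

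List directions are the sign of the median log2 fold change, and the cause of each change of sign was not tested. With library size only, medians changed sign for SRF-MRTF targets (0.0044), focal adhesion adaptors (0.11), oxidative stress (0.028) and the unfolded protein response (0.048). With upper-quartile factors, focal adhesion adaptors stood at 0.0028. With no filter, focal adhesion adaptors stood at 0.0022 and skeletal muscle at 1.18. With the stricter filter, Schwann cell markers stood at -0.31, TGF-beta at -0.022 and YAP-TAZ targets at -0.014. With limma-voom, TGF-beta stood at -0.026, YAP-TAZ at -0.079, MHC class II at -1.25 and integrins at -0.12. With the term for the shared title number, TGF-beta stood at -0.085, YAP-TAZ at -0.019, MHC class II at -1.27 and the gene Saa3 at -0.92. On log2(RPKM + 1), focal adhesion adaptors stood at 0.14, and on log2(RPKM + 0.1) also at 0.14. On log2(RPKM + 1) with no filter, SRF-MRTF targets stood at 0.032, focal adhesion adaptors at 0.024, skeletal muscle at 0.0039 and the unfolded protein response at 0.0072. Without both libraries of the shared title number, TGF-beta stood at -0.36, YAP-TAZ at -0.26, MHC class II at -2.50, integrins at -0.32 and Saa3 at -2.53.

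Leaving out 1 library at a time, medians that changed sign ranged from -0.21 to 0.22 for Schwann cell markers, -0.56 to 0.33 for TGF-beta, -0.18 to 0.41 for YAP-TAZ, -2.75 to 1.12 for MHC class II, -1.84 to 0.49 for endothelial markers, -0.15 to 0.066 for focal adhesion adaptors and -0.13 to 0.45 for integrins. They ranged from -0.70 to 0.74 for interferon-stimulated genes, -2.43 to 2.27 for leukocyte markers, -0.49 to 0.013 for oxidative stress and -0.98 to 0.33 for skeletal muscle. Among genes, H2-Ab1 ranged from -3.06 to 1.30, Rtp4 from -0.77 to 3.05, Saa3 from -4.08 to 4.30 and Slpi from -1.11 to 4.30.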

Other observations

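The ribosome biogenesis and adventitial fibroblast lists and the genes Meg3, Dio3 and Igf2 were chosen after gene values had been seen, and so were the tests on Tgfb1i1, on KO replicate 2, on leukocytes and on other splits for gene and list counts.

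Genes of ribosome biogenesis were higher in libraries labelled KO. All 59 members had a positive log2 fold change, with a median of 0.74, and in 34 of them every KO library lay above every HET library. The list mean (log2, from the 6-library mean) was highest in KO replicate 2, at 0.66. It was 0.02 and 0.38 in KO replicates 1 and 3, and -0.60 to -0.21 in HET. Nop16 had 26.9 ± 6.16 CPM in HET and 59.2 ± 6.46 CPM in KO, and Utp15 had 16.7 ± 2.47 and 35.2 ± 7.43 CPM (SD). The camera p was 9.0e-26, and 0.0932 with an estimated correlation. Markers of adventitial fibroblasts were lower, in 19 of 21 tested members, with a median of -1.92 and a camera p of 9.0e-20 (0.0022 with an estimated correlation). Ly6a had 858 ± 252 CPM in HET and 53.9 ± 52.7 CPM in KO, and Scara5 had 8.59 ± 4.27 and 0.483 ± 0.382 CPM. The list mean was -2.34 (log2, from the 6-library mean) in KO replicate 2, which also stood apart in collagen genes, against -0.46 and -0.97 in KO replicates 1 and 3 and 1.03 to 1.60 in HET. Igf1, Ly6a and C3, which this list holds, had been seen to be lower before it was written. Among the 10 splits of the 6 libraries, 1 gave a list median as far from 0 as the labels, the labels' own, for either list. The median of the difference in mean log2 CPM was 0.71 for ribosome biogenesis (highest other 0.58) and -2.76 for adventitial markers (highest other 1.44), and 10 splits are too few for a share under 0.05. Both lists were written after gene values had been seen, so neither the p-values nor the place of the labels among the splits is independent evidence.

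Single genes, each picked by eye, also varied between libraries. Meg3 stood at 335.5 ± 67.6 CPM in HET, and at 128 and 139.5 CPM in KO replicates 1 and 3 and 0.0775 CPM in KO replicate 2. Dio3 stood at 14.8 to 229.6 CPM in HET and 0.232 to 1.00 CPM in KO. Igf2 stood at 220.3 CPM in KO replicate 2 and 39.4 CPM or less elsewhere.

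Tgfb1i1 was near 0 in KO replicate 2 only. If true KO libraries lack the transcript, a swap of labels between the genotypes would need a library labelled HET without Tgfb1i1, and the lowest stood at 124.8 CPM. If transcript of the targeted allele is counted, that value excludes no swap, so a swap, a single wrong label and an exchange with an outside sample stay open. Another candidate explanation is transcript of the targeted allele counted to the gene in KO replicates 1 and 3, with KO replicate 2 low because its cells are of another state. Of 3459 genes that in all other libraries stood at 0.5 times the lowest Tgfb1i1 value or more, 9 fell as far in KO replicate 2, among them Col1a2, Loxl2 and Meg3. That count lies between bounds that were themselves set after gene values had been seen, so it decides nothing. Without exon values these explanations, and a genotype effect, cannot be told apart.

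KO replicate 2 had low collagen and raised epithelial genes. Replacement of the fibroblasts by keratin-rich epithelial cells that lack Vim would lower Vim along with Col1a2. Vim stood at 84.4% of the mean of the other 5 libraries and Col1a2 at 0.0276%, which argues against such cells only. Cdh1 (14.6 CPM, at most 1.47 elsewhere) and Epcam (5.66 CPM, at most 0.912 elsewhere) were highest there. Thy1 was lowest (0.981 CPM, at least 75.7 elsewhere), so epithelial cells that express Vim stay open. Leukocytes in the culture are argued against by Ptprc at 0 counts there. Another population that expresses Vim, or a change of the fibroblasts themselves with or without the genotype, stays open and was not tested.

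A candidate explanation of the higher ribosome biogenesis genes is growth rate, which S phase genes follow too. With the S phase mean of each library as a covariate, the ribosome biogenesis median was 0.42, 56.4% of its value without it (camera p = 8.8e-13; p = 0.196 with an estimated correlation). A median kept over 50%, with a camera p under 0.05, had been set before this covariate fit as arguing against growth rate. Both were met at the preset correlation. The camera p with an estimated correlation was not under 0.05, a condition that had not been set beforehand. With that condition, growth rate and a separate difference cannot be told apart. The covariate fit replaced an earlier comparison of HET replicate 1 with KO replicate 3 on the same lists. There S phase differed by 0.38 and ribosome biogenesis by -0.63 (log2), which rested on single libraries and decides nothing. A genotype effect stays open.

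Other splits of the 6 libraries gave counts as large as the labels. With edgeR all 10 splits gave 0 genes at the adjusted threshold. At an unadjusted p the labels gave 1511 genes and the highest other split 2236, and 2 of the 10 splits gave as many as the labels. DESeq2 called 240 genes by the labels and 632 in the highest other split, and 3 of the 10 splits gave as many. Camera called 16 lists by the labels and 20 in the highest other split, and 2 of the 10 gave as many. Each of these counts of splits includes the labels' own split. With 10 splits no share can fall under 0.05. The split of HET replicate 1, KO replicate 1 and KO replicate 2 against the rest gave the 2236 and 632 genes, and it also gave 3767 genes whose groups do not overlap, where the labels gave 2729. It was picked as the highest of the 10. On its side with HET replicate 1, S phase means were 0.26 to 1.89, against -1.83 to -0.02 on the other. G2 and M phase means were 0.52 to 1.37 against -2.28 to 0.0054. Inflammatory means were lower there (-1.12 to -0.55 against 0.68 to 0.84), as were MHC class II means (-2.02 to -1.09 against 0.61 to 2.13). These lists were picked for their lack of overlap, and what the split follows was not tested. Leukocytes in HET replicate 2 and KO replicate 3 were weighed, and HET replicate 3, on the same side, stood at 0.0392 CPM of Ptprc, which as a single library decides nothing.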
